A study of Drosophila melanogaster with 16 samples.

How the data were processed

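One table with 9863 genes and 16 libraries was used. Reads were processed with the tools Trimmomatic, TopHat2 (version 2.1.0), HTSeq and limma, per the submitters' processing notes, which give no role, order or settings for them. The libraries came from rRNA-depleted RNA and a stranded kit and were read as 75 bp single ends in 2 technical runs per sample with a mean depth of 30 M reads (M for mega) per sample, per the labels' protocols. This lies under the depth recovered for every library, and whether it counts 1 run or both is not given in the sources used here. The genome build and the annotation of the counting are not given in the sources used here. The expression values are called CPM by the name of the deposited table, but 9 of the 16 library columns sum to more than CPM values of all genes can, so the deposited values are treated as a signal of unstated scaling. The plan made before the data were examined assumed CPM, and the same limma test serves for both. The deposited table also holds the authors' log2 coefficients and mean log2 expression, their moderated t and F statistics as scores, and their p-values and adjusted p-values, from a model that is not stated.

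Every value was a whole multiple of 1 step per library (tolerance 1e-06 reads), so that the step gives the depth in listed genes, 44.9 to 54.2 M reads. Only 2 of the 16 library columns held at least 100 values of up to 20 reads, too few to treat the recovered numbers as counts, so the tests for counts that were planned for recovered reads were not run. No pair of replicates differed by as little as the counting of reads alone would give: the chi-square per degree of freedom lay between 13.9 and 127.

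From the deposited values log2(CPM + 0.5) was computed for genes with at least 1 CPM in at least 4 libraries, which left 9837 genes. limma (version 3.58.1 in R 4.3.3) was fitted to all 16 libraries with 1 mean per group, no covariates, contrasts.fit and eBayes with trend, with 12 residual and 2.97 prior degrees of freedom. Tests were two-sided and p-values were adjusted by Benjamini-Hochberg within each of the 5 comparisons, with 0.05 as the threshold. The comparisons were the diet response in control, the diet response in libraries labelled mutant, the genotype effect on low and on high sugar, and the interaction of genotype and diet. For the tables, the exact tests and the figures Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used beside R.

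Gene lists were fixed before the data were examined: 32 gene lists and 12 lists of cell type markers, of which 43 had at least 3 tested genes. They were tested with limma's camera at a preset correlation between genes of 0.01 and adjusted over the lists within a comparison, and again with an estimated correlation. fry, which asks whether the genes of a list move and compares them with no other genes, served as an alternative. On simulated libraries, the test recovered 84% of genes changed by 0.5 log2 units in the diet response of control and 62.7% in the interaction. The share of false calls was 3.83% to 7.69%. Camera called 99% of lists shifted as much and 0.270% of the others, shares that need not hold for correlated genes.

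Symbols and positions came from an annotation of BDGP6 (Ensembl release 115), in which 9702 of the 9837 tested IDs were found and 135 were not. The genes named were chosen by a rule fixed before the data were examined. It names cwo, sug, cbt, Mondo, per, tim and vri always, then per comparison the 8 genes with the largest rise and the 8 with the largest fall that passed, had at least 5 CPM in the higher group and, for comparisons of 2 groups, no overlap between their libraries, and then up to 4 genes with the smallest adjusted p of each list described. From these a subset was picked for the text after the values were seen. The gene per is not analysed here. Genes named outside the rule are said to be so. The genotype names are those of the labels, and libraries of the allele are called "labelled mutant" because values per gene check nothing about the allele.

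The alternatives planned were other pseudocounts, other filters, median-ratio scaling, quantile normalization, a robust fit, the replicate number as a block, only the 8 libraries compared, and leaving out each library in turn. The alternatives added after the data were seen were a fit without the 4 libraries of high Tweedle score, fits without 4 other libraries, 1 per group, the Tweedle score as a covariate, the level of roX1 as a covariate, and array weights. The Tweedle score is the mean log2(CPM + 0.5) of 15 genes of the Tweedle family in a library, and roX1 is an RNA made in males. Genes near cwo were compared with all other tested genes by Fisher's exact test. Correlations with the Tweedle score within groups were tested over 331776 arrangements of the libraries within their groups, and neighbouring genes over 10000 permutations of gene order.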

Results

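RNA was measured in whole Drosophila melanogaster larvae of a control strain and of the allele cwo B9, which is called mutant in the labels. First-instar larvae fed for 24 h at 25 °C on a low-sugar diet (10% yeast) and, as early second-instar larvae, were moved for 8 h to fresh low-sugar food or to a high-sugar diet (10% yeast and 15% sucrose). The 16 libraries form 4 groups of 4: control on low sugar, control on high sugar, mutant on low sugar and mutant on high sugar. The title of the series names the question: how Clockwork orange, the transcriptional repressor encoded by cwo, takes part in the response of transcription to sugar. Recovered from the step between the values of each library, the depth in listed genes was 44.9 to 54.2 M reads per library (M for mega), with group means of 49.3 ± 3.36, 50.0 ± 1.14, 51.3 ± 3.29 and 50.2 ± 1.13 M reads (SD, n = 4, in the order above). All levels are given as mean CPM ± SD over the 4 libraries of a group (n = 4), and all changes as log2 differences ± SE from limma, two-sided, with p-values adjusted over the 9837 genes tested. For a gene list, the adjusted p is that of camera with a preset correlation between genes of 0.01, followed by that with an estimated correlation, and counts adjusted over the list alone are in the same order as the counts before them. The comparisons, gene lists and main alternatives were fixed before the data were examined. The labels do not say how the replicates arose, so p-values measure the spread between these samples, which may be technical. The leading principal component of the 16 libraries held 46.8% of the variance and the next held 33.4%, and jointly they separated the 4 groups.

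The targeted gene was examined first as a check of the labels. The gene cwo (FBgn0259938, 3R 10388258 to 10400752, plus strand, BDGP6) stood at 57.0 ± 1.53 CPM in control larvae on low sugar and 68.9 ± 3.93 on high sugar. In libraries labelled mutant it stood at 181 ± 28.2 on low sugar and 279 ± 11.4 on high sugar, so it was higher by 1.64 ± 0.09 (adjusted p = 1.07e-09) and by 2.01 ± 0.09 (adjusted p = 9.56e-11). Each of the 8 libraries labelled mutant lay above every control library, the lowest at 139 CPM against a highest control of 72.8. The direction goes against what a label of a mutant would give if the allele removed the RNA. The values per gene do not show which part of the gene the allele changes and check nothing about the allele itself, so the libraries are called "labelled mutant" and every genotype direction rests on that label. The gene white (w), a pigment transporter often used as a marker of transgenes, separated the labels without overlap, at no more than 0.869 CPM in control libraries and no less than 316 CPM in libraries labelled mutant.

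Of other clock genes, tim and Pdp1 were higher in libraries labelled mutant. timeless (tim, FBgn0014396, 2L 3493986 to 3508119), a core clock repressor, rose from 1.32 ± 0.290 to 11.5 ± 0.262 CPM on low sugar and from 5.30 ± 0.390 to 37.0 ± 4.64 on high sugar, changes of 2.73 ± 0.10 and 2.69 ± 0.10 (adjusted p = 1.02e-11 and 1.18e-11). Pdp1, a clock activator with further roles in growth, was higher by 0.58 ± 0.05 and 0.34 ± 0.05 (adjusted p = 6.23e-07 and 1.35e-04). vri, the repressor paired with Pdp1 in the clock, differed by 0.06 ± 0.29 and 0.60 ± 0.29 and passed on neither diet (adjusted p = 0.889 and 0.116), although it passed on high sugar in a fit of only the 8 libraries compared (0.60, adjusted p = 1.18e-04). vri was low throughout, between 1.78 ± 0.410 and 4.63 ± 0.325 CPM. Of 11 measured genes of the circadian clock list, 3 were higher, 1 was lower and 7 did not pass (3 and 1 over the list alone) on low sugar, and 4 were higher, 1 was lower and 6 did not pass (5 and 1 over the list alone) on high sugar. The list passed on neither diet (adjusted p = 0.216, adjusted p = 0.688 with an estimated correlation on low sugar; adjusted p = 0.0648, adjusted p = 0.512 with an estimated correlation on high sugar).

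**Figure D1:**
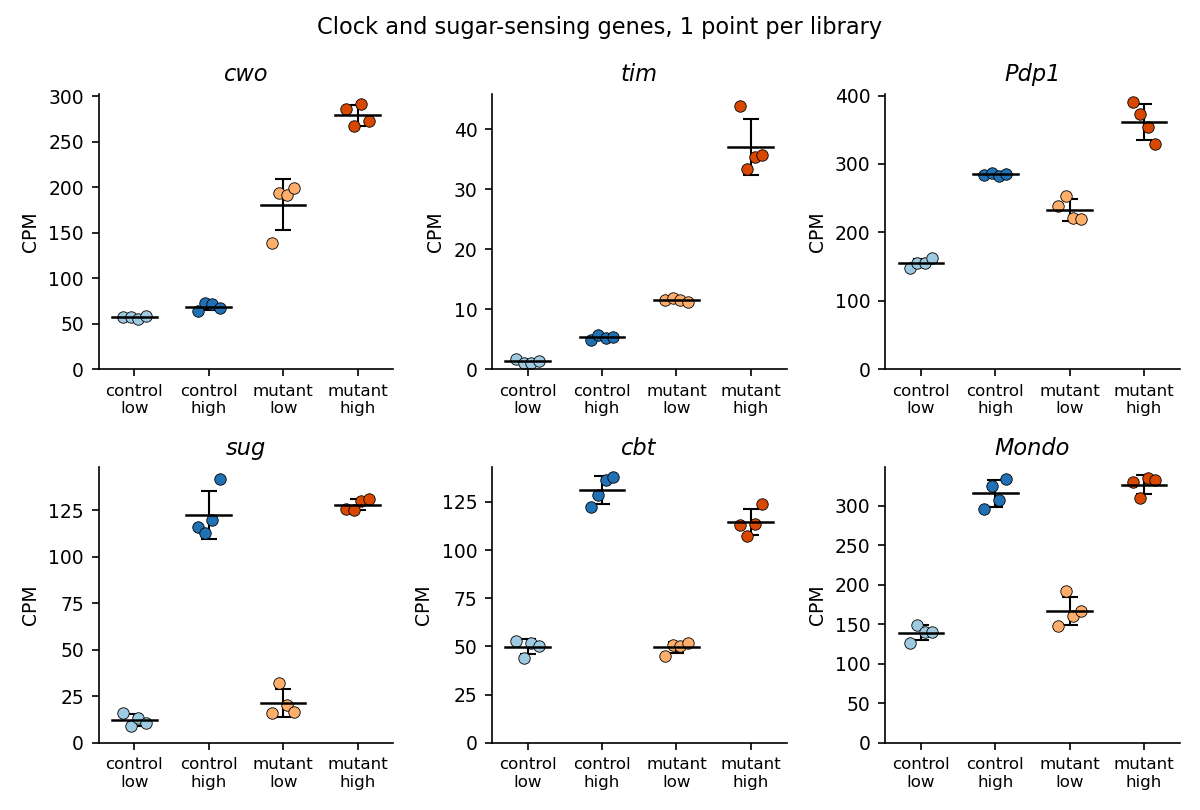
CPM (vertical axis, from 0) of cwo, tim, Pdp1, sug, cbt and Mondo in each of the 16 libraries, with the mean and SD of each group of 4; control libraries are blue, libraries labelled mutant orange, and darker colours mark high sugar. All 8 libraries labelled mutant lie above 138.6 CPM for cwo, and sug lies near 123 and 128 CPM on high sugar in the control and labelled mutant groups.

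In control larvae many genes changed within 8 h on the high-sugar diet. sugarbabe (sug, FBgn0033782, 2R 12924567 to 12930644), a zinc finger transcription factor induced by sugar, rose from 12.2 ± 3.08 to 123 ± 12.9 CPM (3.30 ± 0.19, adjusted p = 1.17e-09). cabut (cbt, FBgn0043364), a zinc finger regulator of the Klf family, rose by 1.39 ± 0.06 and Mondo (FBgn0032940), the sugar-sensing partner of Mlx, rose by 1.18 ± 0.07. tim rose by 1.68 ± 0.10 and cwo by 0.27 ± 0.09, while vri differed by 0.65 ± 0.29 and did not pass (adjusted p = 0.0560). vri passed without control low-sugar library 1 (0.89, adjusted p = 0.0115) or library 3 (0.91, adjusted p = 0.00824). It also passed with median-ratio scaling (0.67, adjusted p = 0.0481), array weights (0.74), roX1 as a covariate (0.81), and without the 4 libraries of high Tweedle score described with the interaction (0.88). Of 7 genes of Mondo-Mlx sugar sensing, 5 rose, none fell and 2 did not pass (5 and 0 over the list alone, adjusted p = 0.0104, adjusted p = 0.470 with an estimated correlation).

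Genes of fat synthesis rose. AcCoAS, which makes acetyl-CoA from acetate, went from 223 ± 25.2 to 1961 ± 153 CPM (3.14 ± 0.12). ACC and FASN1, the acetyl-CoA carboxylase and a fatty acid synthase, rose by 2.42 ± 0.12 and 2.33 ± 0.13, and the desaturase Desat1 rose by 2.03 ± 0.07. Of 14 genes of fatty acid synthesis, 9 rose, 3 fell and 2 did not pass (9 and 3 over the list alone), with a median of 0.89 (adjusted p = 0.00541, adjusted p = 0.470 with an estimated correlation). Zw and Pgd, the oxidative enzymes of the pentose phosphate pathway, rose by 2.32 ± 0.08 and 1.64 ± 0.08. Of 7 genes of that pathway 6 rose, none fell and 1 did not pass (6 and 0 over the list alone, adjusted p = 0.00107, adjusted p = 0.470 with an estimated correlation). Gpo-1 and Gpdh, the enzymes of the glycerophosphate shuttle, rose by 2.42 ± 0.05 and 1.84 ± 0.06, and enolase (Eno) rose from 1676 ± 39.9 to 3103 ± 110.1 CPM. Of 14 glycolysis genes, which include this shuttle, 12 rose and 2 fell (12 and 2 over the list alone, adjusted p = 2.83e-04, adjusted p = 0.470 with an estimated correlation). All 3 measured genes of gluconeogenesis rose, also adjusted over the list alone: CG10924 by 2.27 ± 0.22, PCB by 1.05 ± 0.06 and fbp by 0.78 ± 0.04 (adjusted p = 0.0108, adjusted p = 0.470 with an estimated correlation).

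The 8 largest rises under the rule for named genes included CG1774, from 33.9 ± 3.83 to 959.6 ± 68.3 CPM, the maltase Mal-A7 (4.43 ± 0.21) and the noncoding RNA CR45190 (5.71 ± 0.16). Among the largest falls were urate oxidase (Uro), from 81.4 ± 6.90 to 2.13 ± 1.59 CPM (1.36 ± 0.462 without library 2), and the neighbouring X-linked genes CG14422 (FBgn0029645, X 2943386 to 2944569), from 339.6 ± 192 to 0.212 ± 0.130, and CG32793, from 180.2 ± 80.8 to 4.04 ± 1.99. These X-linked genes lie in 1 cluster of adjacent genes, so reads shared between copies cannot be excluded and their values are uncertain.

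Several groups of the gut and of detoxification rose. The trypsins alphaTry and thetaTry rose by 2.14 ± 0.13 and 2.12 ± 0.13. Of 27 digestive serine proteases 21 rose, none fell and 6 did not pass (21 and 0 over the list alone, adjusted p = 1.41e-06, adjusted p = 0.470 with an estimated correlation). GstE7 rose from 30.0 ± 5.15 to 185 ± 17.6 CPM. Of 34 glutathione S-transferases 19 rose, 5 fell and 10 did not pass (19 and 5 over the list alone, adjusted p = 0.00484, adjusted p = 0.514 with an estimated correlation). Cyp6w1 rose by 2.62 ± 0.18. Of 68 cytochrome P450 genes 39 rose, 12 fell and 17 did not pass (39 and 12 over the list alone, adjusted p = 0.0104, adjusted p = 0.470 with an estimated correlation). Of 16 UDP-glycosyltransferases, 9 rose, 1 fell and 6 did not pass (9 and 1 over the list alone, adjusted p = 0.0193, adjusted p = 0.485 with an estimated correlation).

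Most ribosome biogenesis and proteasome genes fell. Nop56 and fibrillarin (Fib), core proteins of the nucleolar particles that modify ribosomal RNA, fell by 1.55 ± 0.09 and 1.44 ± 0.09. Of 19 genes of ribosome biogenesis 18 fell and 1 rose (18 and 1 over the list alone), with a median of -1.22 (adjusted p = 7.95e-07, adjusted p = 0.470 with an estimated correlation). Rpn11, the deubiquitinase of the proteasome lid, went from 126 ± 3.54 to 87.8 ± 4.07 CPM. Of 33 proteasome genes 31 fell, none rose and 2 did not pass (31 and 0 over the list alone, adjusted p = 1.41e-06, adjusted p = 0.470 with an estimated correlation). Amino acid genes moved in both directions. CG11796, of tyrosine breakdown, changed by -1.44 ± 0.07 and glutamine synthetase Gs1 by 2.36 ± 0.12. Of 18 genes of amino acid catabolism 10 fell, 2 rose and 6 did not pass (10 and 2 over the list alone, adjusted p = 0.0334, adjusted p = 0.470 with an estimated correlation). The phosphoserine phosphatase aay rose from 38.8 ± 12.4 to 403 ± 36.0 CPM while sarcosine dehydrogenase (Sardh) went from 65.3 ± 3.59 to 14.5 ± 2.04. In their list, serine, glycine and one-carbon metabolism, 11 fell, 3 rose and 1 did not pass (11 and 3 over the list alone, adjusted p = 0.0212, adjusted p = 0.470 with an estimated correlation).

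Mitochondrial, cuticle and nervous system genes also moved. Of 65 genes of oxidative phosphorylation, 32 rose, none fell and 33 did not pass (30 and 0 over the list alone), with a median of only 0.12 (adjusted p = 0.00405, adjusted p = 0.676 with an estimated correlation). Of 19 genes of the TCA cycle, 12 rose, 3 fell and 4 did not pass (12 and 4 over the list alone, adjusted p = 0.0334, adjusted p = 0.470 with an estimated correlation). Of 80 cuticle protein genes, 32 rose, 5 fell and 43 did not pass (29 and 5 over the list alone, adjusted p = 0.0218, adjusted p = 0.671 with an estimated correlation), and 28 of the 80 moved within groups with the Tweedle score described with the interaction. Of 28 genes of chitin metabolism 17 rose, 6 fell and 5 did not pass (17 and 6 over the list alone, adjusted p = 0.0379, adjusted p = 0.470 with an estimated correlation). The neuron marker Gad1 rose by 0.60 ± 0.06 and the glutamate transporter Eaat1, a glia marker, by 1.39 ± 0.06. Of 12 neuron markers, 11 rose, none fell and 1 did not pass (11 and 0 over the list alone, adjusted p = 0.00541, adjusted p = 0.525 with an estimated correlation). Of 6 glia markers 5 rose, none fell and 1 did not pass (5 and 0 over the list alone, adjusted p = 0.0158, adjusted p = 0.470 with an estimated correlation).

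In total, limma called 6678 genes in control larvae, of which 3258 rose and 3420 fell, and 508 rose and 437 fell at least 2-fold. In the authors' deposited table the corresponding count was 6695. Camera called 19 of 43 lists at the preset correlation and none with an estimated correlation, where 2 had an unadjusted p under 0.05.

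In libraries labelled mutant, sug rose from 21.3 ± 7.58 to 128 ± 2.92 CPM (2.62 ± 0.19, adjusted p = 3.46e-08), cbt by 1.2026 ± 0.06 and Mondo by 0.97 ± 0.07. cwo rose by 0.64 ± 0.09, tim by 1.63 ± 0.10 and vri by 1.19 ± 0.29 (adjusted p = 2.52e-05, 5.28e-09 and 0.00276). Of 11 clock genes, 7 rose, 3 fell and 1 did not pass (7 and 3 over the list alone, adjusted p = 0.0356, adjusted p = 0.319 with an estimated correlation). Of 7 genes of Mondo-Mlx sugar sensing 4 rose, none fell and 3 did not pass (4 and 0 over the list alone, adjusted p = 0.00157, adjusted p = 0.309 with an estimated correlation).

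Fat and sugar genes again mostly rose. AcCoAS, ACC, Desat1 and the ATP citrate lyase gene ATPCL rose by 2.18 ± 0.12, 1.77 ± 0.12, 1.84 ± 0.07 and 1.19 ± 0.09. Of 14 genes of fatty acid synthesis 8 rose, 3 fell and 3 did not pass (8 and 3 over the list alone, adjusted p = 0.00188, adjusted p = 0.319 with an estimated correlation). All 7 measured genes of the pentose phosphate pathway rose, also adjusted over the list alone, with Zw at 1.93 ± 0.08 and Pgd at 1.4962 ± 0.08 (adjusted p = 1.73e-06, adjusted p = 0.309 with an estimated correlation). The isomerase Pgi rose by 1.34 ± 0.06, Gpdh by 1.37 ± 0.06 and Gpo-1 by 1.45 ± 0.05. Of 14 glycolysis genes 12 rose and 2 fell (12 and 2 over the list alone, adjusted p = 1.73e-06, adjusted p = 0.309 with an estimated correlation). Glycogen genes rose as well. The branching enzyme AGBE went from 138 ± 12.5 to 541 ± 33.0 CPM, UGP from 135 ± 3.59 to 329.8 ± 5.95, and Gbs-70E, a glycogen-targeting subunit of protein phosphatase, from 25.5 ± 3.82 to 189 ± 21.0. Of 13 genes of trehalose, glycogen and polyol metabolism, 8 rose, 3 fell and 2 did not pass (9 and 3 over the list alone, adjusted p = 0.0228, adjusted p = 0.473 with an estimated correlation).

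Among nutrient hormones, the activin ligand daw rose by 1.37 ± 0.08 and the adipokinetic hormone receptor AkhR rose by 1.13 ± 0.09. Of 16 genes of insulin, AKH and nutrient hormones, 7 rose, 2 fell and 7 did not pass (7 and 2 over the list alone, adjusted p = 0.0335, adjusted p = 0.319 with an estimated correlation). Among the largest changes, CG4269 rose from 1.69 ± 0.333 to 39.7 ± 6.45 CPM and CR45190 from 2.29 ± 0.499 to 25.6 ± 3.14. The amylases Amy-p and Amy-d, near-identical copies whose reads cannot be told apart with certainty, fell by 3.40 ± 0.08 and 3.29 ± 0.10. The trypsin alphaTry rose by 1.1999 ± 0.13 and the protease Jon65Ai from 86.8 ± 16.3 to 407 ± 30.4 CPM. Of 27 digestive serine proteases, 18 rose, 1 fell and 8 did not pass (18 and 1 over the list alone, adjusted p = 7.42e-06, adjusted p = 0.473 with an estimated correlation). Of 16 UDP-glycosyltransferases, 10 rose, 2 fell and 4 did not pass (10 and 2 over the list alone, adjusted p = 0.00446, adjusted p = 0.473 with an estimated correlation).

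Breakdown genes mostly fell, Uro from 63.8 ± 17.8 to 0.356 ± 0.248 CPM and xanthine dehydrogenase (ry) from 28.2 ± 1.42 to 13.3 ± 1.13. Of 11 genes of purine synthesis and uric acid 7 fell, 1 rose and 3 did not pass (8 and 2 over the list alone, adjusted p = 0.0207, adjusted p = 0.319 with an estimated correlation). CG11796 fell by 2.27 ± 0.07 and glutamate dehydrogenase (Gdh) by 1.13 ± 0.06. Of 18 genes of amino acid catabolism 12 fell, 4 rose and 2 did not pass (12 and 4 over the list alone, adjusted p = 0.00157, adjusted p = 0.0819 with an estimated correlation). In serine, glycine and one-carbon metabolism 11 fell, 3 rose and 1 did not pass (11 and 3 over the list alone, adjusted p = 0.00188, adjusted p = 0.309 with an estimated correlation). The acyl-CoA dehydrogenase CG12262 and the thiolase yip2 fell by 1.92 ± 0.12 and 0.98 ± 0.07. Of 17 genes of fatty acid oxidation 11 fell, 2 rose and 4 did not pass (12 and 2 over the list alone, adjusted p = 0.00424, adjusted p = 0.319 with an estimated correlation). Nop56 and Fib fell by 0.78 ± 0.09 and 0.85 ± 0.09. Of 19 genes of ribosome biogenesis 17 fell, 1 rose and 1 did not pass (17 and 1 over the list alone, adjusted p = 1.73e-06, adjusted p = 0.473 with an estimated correlation). Rpn11 fell by 0.35 ± 0.05. Of 33 proteasome genes 31 fell, none rose and 2 did not pass (31 and 0 over the list alone, adjusted p = 1.73e-06, adjusted p = 0.473 with an estimated correlation).

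The oxidative phosphorylation list had a median of 0.08: 13 rose, none fell and 52 did not pass (4 and 0 over the list alone, adjusted p = 0.00188, adjusted p = 0.805 with an estimated correlation). With quantile normalization its members ATPsynbeta and SdhA turned from 0.15 ± 0.04 and 0.11 ± 0.03 to -0.0241 and -0.00882. Of 12 neuron markers, 7 rose, none fell and 5 did not pass (7 and 0 over the list alone, adjusted p = 0.0228, adjusted p = 0.69980 with an estimated correlation). Of 6 glia markers 3 rose, none fell and 3 did not pass (3 and 0 over the list alone, adjusted p = 0.0228, adjusted p = 0.319 with an estimated correlation). limma called 5121 genes, 2215 up and 2906 down, with 227 up and 183 down at least 2-fold, and the authors' deposited table called 5111. Camera called 18 lists, and none with an estimated correlation, where 6 had an unadjusted p under 0.05.

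**Figure D2:**
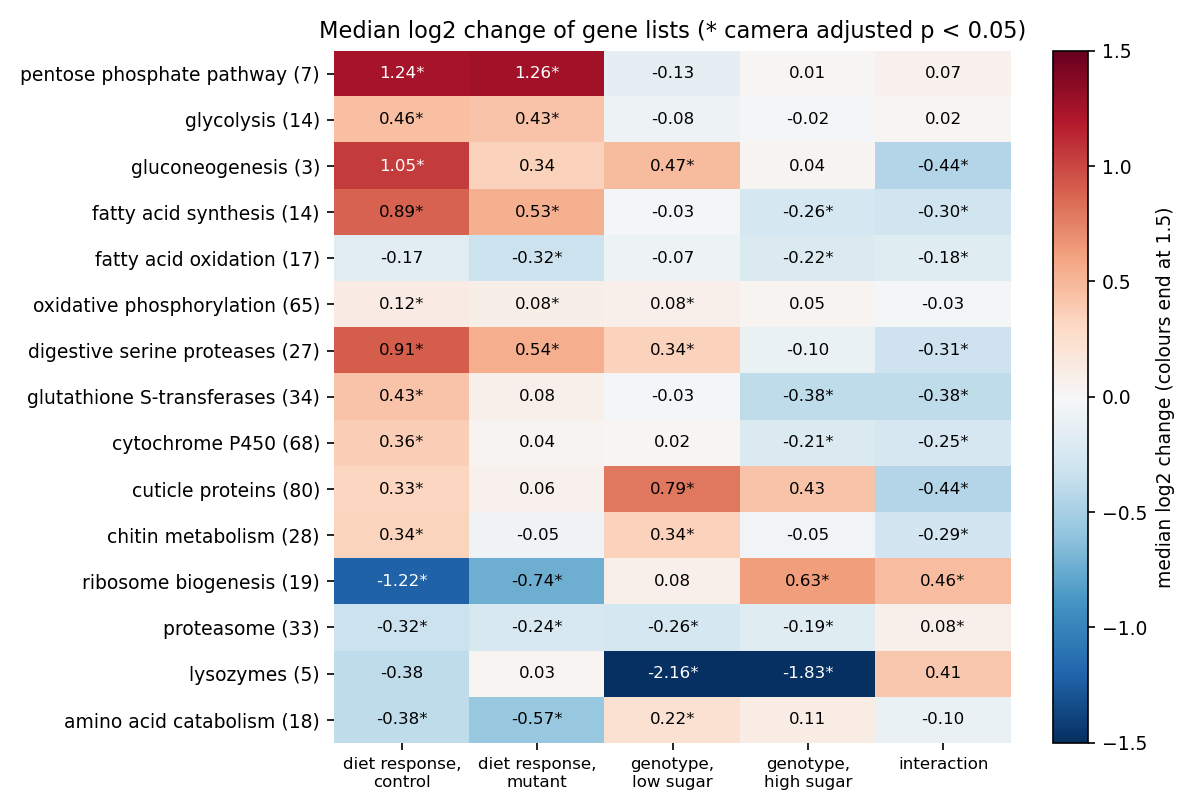
Median log2 change of 15 gene lists (vertical axis, with the number of tested genes) in the 5 comparisons (horizontal axis, where mutant means libraries labelled mutant), with an asterisk where the camera adjusted p was under 0.05 at the preset correlation. Ribosome biogenesis had a median of -1.22 in the diet response of control and -0.74 in libraries labelled mutant, and no asterisk holds with an estimated correlation.

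On low sugar, libraries labelled mutant were compared with control, and each direction rests on that label. Higher in libraries labelled mutant were w (8.74 ± 0.16), phu, from 10.7 ± 12.989 (4.22 ± 1.70 without library 1) to 421 ± 37.6 CPM, nol (4.72 ± 0.30) and Hsp70Bb (3.14 ± 0.25), a heat shock gene with near-identical copies, so that its value is uncertain. Lower were CG10514 (FBgn0039312, 3R 25278427 to 25279846), from 135 ± 9.73 to 0.0297 ± 0.0257 CPM, its neighbour CG11892, from 67.6 ± 1.4971 to 0.0583 ± 0.0458, and the X-linked CG14422, from 339.6 ± 192 to 1.85 ± 2.12 (0.813 ± 0.583 without library 1). Cyp4p2 went from 57.1 ± 4.20 to 1.39 ± 1.63 CPM (0.635 ± 0.737 without library 1). Of the genes of sugar sensing, sug was higher by 0.75 ± 0.19 (adjusted p = 0.00485) and Mondo by 0.26 ± 0.07 (adjusted p = 0.00735), while cbt differed by -0.01 ± 0.06 and did not pass (adjusted p = 0.950). The call of Mondo ended without the 4 libraries of high Tweedle score (0.21, adjusted p = 0.0600).

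Lysozyme genes were lower. LysD and LysC went from 112 ± 17.7 to 0.260 ± 0.0282 CPM and from 14.7 ± 2.36 to 0.0242 ± 0.00954, and LysB and LysE differed by -2.16 ± 0.20 and -1.44 ± 0.17. These are adjacent near-identical genes, so the share of reads given to each is uncertain. Of 5 lysozymes, 4 were lower, none was higher and 1 did not pass (4 and 0 over the list alone, adjusted p = 4.54e-05, adjusted p = 0.447 with an estimated correlation). The salivary gland genes ng1, ng2 and ng3, also adjacent and similar in sequence, differed by -4.11 ± 0.17, -5.28 ± 0.14 and -5.61 ± 0.23. Of 4 salivary gland markers, 3 were lower and 1 was higher (3 and 1 over the list alone, adjusted p = 0.00208, adjusted p = 0.447 with an estimated correlation). The member that was higher is the transcription factor fkh, at 0.22 ± 0.08 (adjusted p = 0.0464), a call that ended when 1 library was left out among control low-sugar libraries 1, 2 and 4 or labelled mutant low-sugar libraries 2, 3 and 4 (0.17, 0.23, 0.22, 0.19, 0.19 and 0.16). It also ended with quantile normalization (0.18), in a fit of only the 8 libraries compared (0.22, adjusted p = 0.145), with the Tweedle score (0.20) or roX1 (0.18) as a covariate and without the 4 libraries of high Tweedle score (0.11).

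Digestive genes were higher: betaTry went from 207 ± 20.8 to 959 ± 67.7 CPM, Jon44E from 135 ± 9.22 to 560.0 ± 54.2, and alphaTry and the maltase Mal-A1 differed by 1.47 ± 0.13 and 1.43 ± 0.12. Of 27 digestive serine proteases, 15 were higher, 5 were lower and 7 did not pass (15 and 5 over the list alone, adjusted p = 0.00366, adjusted p = 0.750 with an estimated correlation). Midgut enterocyte markers, of which 6 of 9 stand in the protease or amylase list, moved with them: of 9, 5 were higher, none was lower and 4 did not pass (5 and 0 over the list alone), with a median of 0.84 (adjusted p = 0.00694, adjusted p = 0.584 with an estimated correlation). Among cuticle genes Cpr60D and Cpr67Fa2 were higher by 1.32 ± 0.10 and 1.57 ± 0.09, while Cpr67Fa1, a neighbour of similar sequence and so uncertain, differed by -1.73 ± 0.10. Of 80 cuticle proteins, 43 were higher, 10 were lower and 27 did not pass (44 and 10 over the list alone, adjusted p = 4.54e-05, adjusted p = 0.688 with an estimated correlation), and 28 of the 80 moved within groups with the Tweedle score. In chitin metabolism, of 28 genes, 17 were higher, 4 were lower and 7 did not pass (17 and 4 over the list alone, adjusted p = 0.0170, adjusted p = 0.584 with an estimated correlation).

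Some amino acid and mitochondrial genes were higher. Gdh went from 1538 ± 68.6 to 2703 ± 254.73 CPM, the kynurenine enzyme cn from 8.23 ± 0.771 to 19.4 ± 2.21 and hgo, of tyrosine breakdown, from 20.4 ± 1.94 to 41.8 ± 3.67. Of 18 genes of amino acid catabolism, 10 were higher, 1 was lower and 7 did not pass (10 and 1 over the list alone, adjusted p = 0.00694, adjusted p = 0.209 with an estimated correlation). The oxoglutarate dehydrogenase gene Nc73EF was higher by 0.52 ± 0.04 and SdhC by 0.25 ± 0.04. Of 19 genes of the TCA cycle, 12 were higher, none was lower and 7 did not pass (13 and 0 over the list alone, adjusted p = 0.00366, adjusted p = 0.584 with an estimated correlation), and in oxidative phosphorylation, of 65 genes, 22 were higher, none was lower and 43 did not pass (20 and 0 over the list alone, adjusted p = 0.0138, adjusted p = 0.872 with an estimated correlation). In gluconeogenesis fbp and PCB were higher by 0.61 ± 0.04 and 0.37 ± 0.06: of 3, 2 were higher, none was lower and 1 did not pass (3 and 0 over the list alone, adjusted p = 0.0425, adjusted p = 0.584 with an estimated correlation). Proteasome genes were lower, with Rpn11 at -0.46 ± 0.05 and Rpn5 at -0.41 ± 0.05: of 33, 29 were lower, none was higher and 4 did not pass (29 and 0 over the list alone, adjusted p = 5.85e-09, adjusted p = 0.584 with an estimated correlation). The ribosomal protein gene RpL34a differed by -0.38 ± 0.05. Of 89 cytosolic ribosomal proteins 19 were lower, 1 was higher and 69 did not pass (8 and 1 over the list alone), with a median of -0.09 (adjusted p = 0.00195, adjusted p = 0.869 with an estimated correlation). Of 10 heat shock genes, 4 were higher, none was lower and 6 did not pass (4 and 0 over the list alone, adjusted p = 0.0478, adjusted p = 0.688 with an estimated correlation). Of 12 neuron markers 6 were higher, none was lower and 6 did not pass (6 and 0 over the list alone, adjusted p = 0.0258, adjusted p = 0.750 with an estimated correlation).

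limma called 4313 genes on low sugar, 2268 higher and 2045 lower in libraries labelled mutant, with 358 and 199 at least 2-fold, and the authors' deposited table called 4346. Camera called 14 lists, and none with an estimated correlation, where 3 had an unadjusted p under 0.05. The strains differed in w as well as in cwo, so background variants and the allele cannot be separated by this contrast.

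On high sugar w was again higher, from 0.449 ± 0.29956 to 539.7 ± 9.84 CPM in libraries labelled mutant, as were phu (6.18 ± 0.50), nol (4.31 ± 0.30) and, with uncertain reads, Hsp70Bb (4.34 ± 0.25). CG10474 went from 6.63 ± 2.71 to 289 ± 65.3 CPM and Alp2 differed by 4.01 ± 0.14. Lower were LysD, LysC and LysB, at -6.57 ± 0.12, -4.44 ± 0.12 and -1.83 ± 0.20, all uncertain as near-identical copies, and the salivary genes ng1, ng2 and ng3, at -5.14 ± 0.17, -6.37 ± 0.14 and -6.28 ± 0.23. CG10514 and CG11892 differed by -5.65 ± 0.16 and -5.90 ± 0.19. Of the sensors of sugar, sug differed by 0.07 ± 0.19 and Mondo by 0.05 ± 0.07, and neither passed (adjusted p = 0.811 and 0.604). cbt was lower, at -0.20 ± 0.06 (adjusted p = 0.0233), a call that ended without control high-sugar library 3 or 4 or labelled mutant library 1 or 2 (-0.18, -0.17, -0.19 and -0.17), without the 4 libraries of high Tweedle score (-0.17) or with roX1 as a covariate (-0.18).

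Ribosome biogenesis genes were higher in libraries labelled mutant. ppan went from 21.0 ± 2.02 to 38.0 ± 2.13 CPM, the growth regulator Myc from 105 ± 5.77 to 163 ± 13.9 and nclb from 66.2 ± 6.59 to 113 ± 4.76. Of 19 genes, 18 were higher, none was lower and 1 did not pass (18 and 0 over the list alone, adjusted p = 1.82e-08, adjusted p = 0.512 with an estimated correlation). Genes of P450s and glutathione S-transferases were lower, with Cyp28d2 going from 126 ± 22.7 to 5.21 ± 0.291 CPM, Cyp6a17 differing by -1.97 ± 0.10, and GstE5, GstE1 and GstD8 by -2.03 ± 0.08, -1.88 ± 0.15 and -1.79 ± 0.17. Of 68 cytochrome P450 genes, 35 were lower, 12 were higher and 21 did not pass (35 and 12 over the list alone, adjusted p = 3.12e-04, adjusted p = 0.512 with an estimated correlation). Of 34 glutathione S-transferases, 21 were lower, 5 were higher and 8 did not pass (21 and 5 over the list alone, adjusted p = 1.22e-04, adjusted p = 0.554 with an estimated correlation). Of 16 UDP-glycosyltransferases, 8 were lower, 4 were higher and 4 did not pass (8 and 4 over the list alone), and the list did not pass (adjusted p = 0.474). In fat synthesis, ATPCL went from 2189 ± 133 to 906 ± 57.3 CPM and FASN2 from 132 ± 7.32 to 65.3 ± 6.55. The lipid regulator SREBP went from 315 ± 9.54 to 227 ± 5.33. Of 14 genes, 7 were lower, none was higher and 7 did not pass (7 and 0 over the list alone, adjusted p = 0.00363, adjusted p = 0.512 with an estimated correlation). In fatty acid oxidation the acyl-CoA oxidase Acox57D-d differed by -1.11 ± 0.09 and yip2 by -0.53 ± 0.07: of 17, 10 were lower, none was higher and 7 did not pass (10 and 0 over the list alone, adjusted p = 2.13e-04, adjusted p = 0.344 with an estimated correlation).

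Of 5 lysozymes, 5 were lower and none was higher (5 and 0 over the list alone, adjusted p = 8.51e-05, adjusted p = 0.512 with an estimated correlation). The call of LysS (-0.42 ± 0.12) ended without the 4 libraries of high Tweedle score (-0.26, adjusted p = 0.0569) and with roX1 as a covariate (-0.26, adjusted p = 0.101). Of 4 salivary gland markers, 3 were lower, none was higher and 1 did not pass (3 and 0 over the list alone, adjusted p = 1.22e-04, adjusted p = 0.344 with an estimated correlation), with fkh at 0.01 (adjusted p = 0.962). Rpn5 differed by -0.34 ± 0.05. Of 33 proteasome genes 23 were lower, none was higher and 10 did not pass (24 and 0 over the list alone, adjusted p = 1.10e-05, adjusted p = 0.664 with an estimated correlation). In cytosolic ribosomal proteins, of 89 genes, 18 were lower, 2 were higher and 69 did not pass (13 and 2 over the list alone, adjusted p = 7.92e-04, adjusted p = 0.873 with an estimated correlation). The muscle genes Mlc2, up and Mf differed by -0.33 ± 0.04, -0.36 ± 0.04 and -0.40 ± 0.05. Of 11 muscle markers 7 were lower, 1 was higher and 3 did not pass (7 and 1 over the list alone, adjusted p = 0.0183, adjusted p = 0.857 with an estimated correlation). limma called 3934 genes, 2073 higher and 1861 lower, with 221 and 203 at least 2-fold, and the authors' deposited table called 3925. Camera called 10 lists, and none with an estimated correlation, where 3 had an unadjusted p under 0.05.

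The genotype effects on the 2 diets had r = 0.798 and Spearman's rho = 0.612 across genes, which are not independent replicates, and of 2400 genes called on both diets 2269 had the same sign. Genes near cwo were compared with others, as linked variants can differ. Within 1 Mb, 56.7% of 217 genes were called on low sugar against 43.6% elsewhere, an odds ratio of 1.69 (95% interval 1.28 to 2.25, Fisher's exact test, two-sided, adjusted p over 6 tests = 0.000814). It was 1.32 on high sugar and 1.45 for the interaction (exact test, adjusted p = 0.0896 and 0.0824). The former passed without control high-sugar library 2 (1.39, adjusted p = 0.0368) and with median-ratio scaling (1.37, adjusted p = 0.0493). The latter passed without control low-sugar library 4, control high-sugar library 2 or labelled mutant low-sugar library 4 (1.57, 1.58 and 1.56, adjusted p = 0.0372, 0.0201 and 0.0398), with median-ratio scaling (1.5033), roX1 as a covariate (1.53) and array weights (1.55). Within 5 Mb the odds ratios were 1.08, 1.03 and 1.18 (exact test, adjusted p = 0.340, 0.649 and 0.0896). The call on low sugar ended without labelled mutant library 1 (1.35, exact test, adjusted p = 0.0856) or 2 (1.43, adjusted p = 0.0567), with quantile normalization (1.42) and without the 4 libraries of high Tweedle score (1.28). The tests take neighbours as independent, so p and interval may be too small.

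The interaction asks whether the diet response itself differs between genotypes, and its sign is that of the response in libraries labelled mutant minus that in control. CG10924 (FBgn0034356, 2R 18527430 to 18535749), annotated as a phosphoenolpyruvate carboxykinase, rose from 11.9 ± 5.54 to 55.8 ± 8.25 CPM with sugar in control and went from 15.7 ± 2.36 to 10.4 ± 0.675 in libraries labelled mutant (interaction -2.83 ± 0.30, adjusted p = 3.50e-05). With fbp (-0.44 ± 0.06) and PCB (-0.34 ± 0.08), all 3 measured genes of gluconeogenesis had a negative interaction, also adjusted over the list alone (adjusted p = 5.63e-04, adjusted p = 0.323 with an estimated correlation). GstD8 rose from 9.80 ± 2.08 to 51.3 ± 14.5 CPM in control and differed between 10.7 ± 1.84 and 14.2 ± 0.895 in libraries labelled mutant (interaction -1.92 ± 0.24), and the metal-binding MtnC, the maltase Mal-A7 and the noncoding CR45190 had interactions of -2.04 ± 0.23, -1.94 ± 0.30 and -2.48 ± 0.22. CG14422, CG32793 and CG14424, uncertain as 1 cluster, fell in control and had interactions of 7.32 ± 0.69, 3.35 ± 0.51 and 3.94 ± 0.77. In libraries labelled mutant CG14422 and CG14424 were too low on low sugar to fall as far. CG10514 (interaction 2.35 ± 0.22) stood at 0.0297 ± 0.0257 and 0.114 ± 0.111 CPM (0.0666 ± 0.0697 without library 4) there, where the added 0.5 CPM understates changes.

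**Figure D3:**
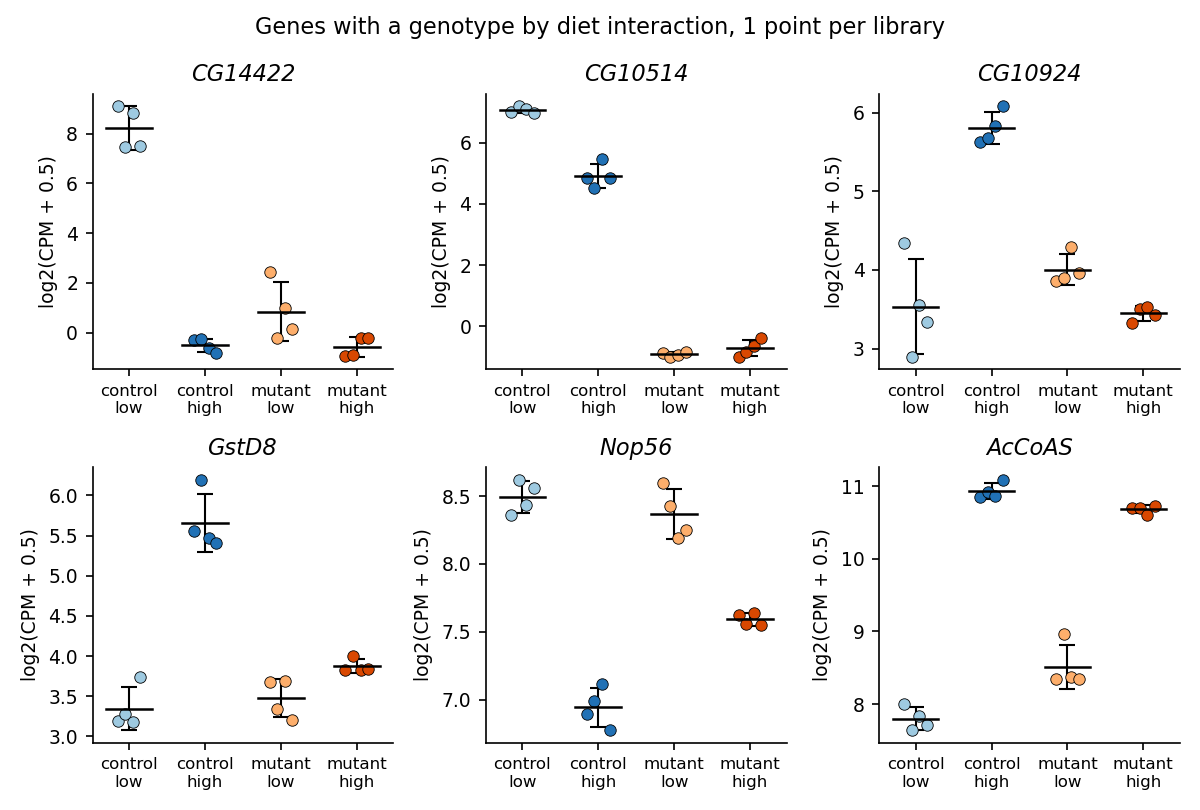
log2(CPM + 0.5) (vertical axis) of 6 genes with an interaction in each of the 16 libraries, with the mean and SD of each group of 4; control libraries are blue, libraries labelled mutant orange, and darker colours mark high sugar. GstD8 rose by 2.31 in control and differed by 0.40 in libraries labelled mutant.

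Of the clock and sugar-sensing genes named here only Pdp1 passed. The interaction was -0.69 ± 0.27 for sug (adjusted p = 0.0947), -0.19 ± 0.09 for cbt (0.168), -0.21 ± 0.10 for Mondo (0.167), -0.05 ± 0.14 for tim (0.858), 0.54 ± 0.41 for vri (0.399) and 0.37 ± 0.13 for cwo (0.0574). sug passed without control low-sugar library 1 (-0.82) or labelled mutant low-sugar library 1 (-0.81), Mondo without the latter (-0.26), and cwo without labelled mutant low-sugar library 1 (0.25) or 4 (0.42). cwo also passed with median-ratio scaling (0.38, adjusted p = 0.0439) and with the Tweedle score as a covariate (0.37, adjusted p = 0.0427), and with array weights both cwo (0.29) and sug (-0.83) passed. With a pseudocount of 2 CPM the interaction of tim turned to 0.38 and passed (adjusted p = 0.0246). Pdp1 passed at -0.24 ± 0.08 (adjusted p = 0.0459), a call that held in 4 of the 16 fits that left out 1 library (without control low-sugar library 4, labelled mutant low-sugar library 3 or 4, or labelled mutant high-sugar library 1), with values from -0.28 to -0.20. The call of Pdp1 also ended with median-ratio scaling (-0.23, adjusted p = 0.0609), the robust fit (-0.24, adjusted p = 0.0506), roX1 as a covariate (-0.24) and array weights (-0.21).

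Several groups had negative interactions. Cyp12a5 and Cyp12a4, neighbours of similar sequence and so uncertain, had interactions of -1.44 ± 0.15 and -0.9963 ± 0.07, and Cyp6g1 of -1.14 ± 0.12. Cyp12a4 rose by 0.60 in control and fell by 0.40 in libraries labelled mutant, and Cyp6g1 fell in both (-0.62 and -1.76). Of 68 cytochrome P450 genes, 22 were negative, 2 were positive and 44 did not pass (27 and 4 over the list alone, adjusted p = 4.45e-06, adjusted p = 0.323 with an estimated correlation). GstE7 rose less, with an interaction of -1.06 ± 0.15, and GstZ2 fell more (-0.59 and -1.16, interaction -0.57 ± 0.07). Of 34 glutathione S-transferases 15 were negative, none was positive and 19 did not pass (18 and 1 over the list alone, adjusted p = 2.14e-08, adjusted p = 0.323 with an estimated correlation). The trypsins alphaTry, epsilonTry and thetaTry had -0.94 ± 0.18, -1.05 ± 0.14 and -1.0007 ± 0.18. Of 27 digestive proteases 7 were negative, 1 was positive and 19 did not pass (8 and 1 over the list alone, adjusted p = 5.59e-04, adjusted p = 0.777 with an estimated correlation). Midgut enterocyte markers, Mal-A1 among them (-1.57 ± 0.17), which did not pass as a list in control, moved with these: of 9, 3 were negative, 1 was positive and 5 did not pass (4 and 1 over the list alone, adjusted p = 0.0307, adjusted p = 0.682 with an estimated correlation). AcCoAS, ACC and FASN2 had -0.96 ± 0.17, -0.65 ± 0.17 and -0.68 ± 0.18. Of 14 genes of fatty acid synthesis 7 were negative, none was positive and 7 did not pass (8 and 1 over the list alone, adjusted p = 0.00828, adjusted p = 0.422 with an estimated correlation). Fatty acid oxidation did not pass as a list in control, where 8 genes fell and 6 rose (adjusted p = 0.444). In this list whd, the carnitine palmitoyltransferase, had an interaction of -0.69 ± 0.18 and yip2, which fell in both (-0.43 and -0.98), of -0.55 ± 0.10: of 17 genes, 6 were negative, 1 was positive and 10 did not pass (6 and 1 over the list alone, adjusted p = 0.0115, adjusted p = 0.367 with an estimated correlation).

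Cuticle and chitin genes were also mostly negative where they passed. Lcp2 and Lcp4 had interactions of -2.11 ± 0.21 and -0.77 ± 0.13, Cpr97Eb of -1.10 ± 0.16, and the chitin-binding obst-B of -0.82 ± 0.11. Of 80 cuticle proteins, 18 were negative, 2 were positive and 60 did not pass (18 and 2 over the list alone, adjusted p = 1.92e-04, adjusted p = 0.777 with an estimated correlation), and 28 of the 80 moved within groups with the Tweedle score. Of 28 genes of chitin metabolism 8 were negative, 1 was positive and 19 did not pass (13 and 1 over the list alone, adjusted p = 1.32e-04, adjusted p = 0.323 with an estimated correlation). Epidermis and cuticle markers, which share Lcp2 and Lcp4 with the cuticle list, moved with them: of 6, 3 were negative, none was positive and 3 did not pass (3 and 0 over the list alone, adjusted p = 0.00143, adjusted p = 0.323 with an estimated correlation). Of 4 salivary gland markers, 2 were negative, none was positive and 2 did not pass (2 and 0 over the list alone, adjusted p = 0.0174, adjusted p = 0.367 with an estimated correlation). The neuron genes Gad1 and nrv3 had -0.35 ± 0.09 and -0.30 ± 0.07. Of 12 neuron markers 3 were negative, none was positive and 9 did not pass (3 and 0 over the list alone, adjusted p = 0.0174, adjusted p = 0.812 with an estimated correlation). Ribosome biogenesis genes, which fell with sugar, fell less in libraries labelled mutant: Nop56, nop5 and Surf6 had positive interactions of 0.77 ± 0.12, 0.66 ± 0.12 and 0.61 ± 0.13. Of 19 genes 16 were positive, 1 was negative and 2 did not pass (16 and 1 over the list alone, adjusted p = 2.26e-08, adjusted p = 0.440 with an estimated correlation). The proteasome list passed with a median of 0.08, although of 33 genes 1 was positive, none was negative and 32 did not pass (0 and 0 over the list alone, adjusted p = 0.0238, adjusted p = 0.825 with an estimated correlation). The call of that gene, Rpn6 (0.16 ± 0.05, adjusted p = 0.0456), held in the fits without control high-sugar library 1, labelled mutant low-sugar library 1 or labelled mutant high-sugar library 3. It ended in the other 13 that left out 1 library (0.14 to 0.17), with median-ratio scaling, in the robust fit, with roX1 as a covariate and without the 4 libraries of high Tweedle score (0.17, 0.16, 0.16 and 0.16).

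limma called 1659 genes with an interaction, 779 positive and 880 negative, with 52 and 105 at least 2-fold, a contrast that was not among the columns of the authors' deposited table. Camera called 14 lists, and none with an estimated correlation, where 6 had an unadjusted p under 0.05. Across genes, which are not independent replicates, the diet responses of the genotypes had r = 0.857 and Spearman's rho = 0.861, and of 4570 genes called in both 4517 had the same sign. The response in libraries labelled mutant was smaller: with the error removed, the SD of its log2 changes was 0.466 against 0.668 in control, a ratio of 0.698. Of 7125 genes with an average diet effect, 1516 had an interaction and 1358 of these (89.6%) went against the diet effect. Among 614 genes with an average diet effect of at least 2-fold, the median response in libraries labelled mutant was 70.3% of that in control. On low sugar the genotype effect had a slope of 0.317 on the average diet effect (r = 0.302), and on high sugar -0.041 (r = -0.042). Simulated libraries (low-sugar r -0.088 to 0.128) lack the effects that link these slopes and are no null.

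In 4 libraries, 1 per group, genes of the Tweedle family of cuticle proteins stood more than 1 log2 unit above the mean of their group (control low-sugar library 1, control high-sugar library 4, and labelled mutant low-sugar library 4 and high-sugar library 3). Within groups, 28 of 80 cuticle proteins moved with the mean of these genes, the Tweedle score, and none against it. Of the 65 outside the score 18 did (camera on these, unadjusted p = 7.32e-18, 0.00729 with an estimated correlation). Without the 4 libraries limma called 790 genes with an interaction, 36.1% positive against 47.0% with all libraries. Leaving out 4 other libraries, 1 per group, gave 529 to 1963 genes over the 81 choices, with a median of 690, and 50 of the 81 called no more than 790, so a count this low is not particular to the libraries of high Tweedle score. Without the latter the interactions of ACC, FASN2, PCB, Pdp1, Gad1 and nrv3 were -0.59 ± 0.21, -0.55 ± 0.16, -0.37 ± 0.11, -0.23 ± 0.09, -0.33 ± 0.11 and -0.28 ± 0.08, each within 1 SE of the value with all libraries, and did not pass (adjusted p = 0.119, 0.0523, 0.0556, 0.152, 0.0851 and 0.0557). Without 4 other libraries these calls ended in 46, 54, 45, 78, 50 and 40 of the 81 choices. In each of them FASN2 was farther from 0 (-0.88 to -0.59) than without the libraries of high Tweedle score. ACC and PCB also did not pass with quantile normalization (-0.52 and -0.17, adjusted p = 0.0543 and 0.176).

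**Figure D4:**
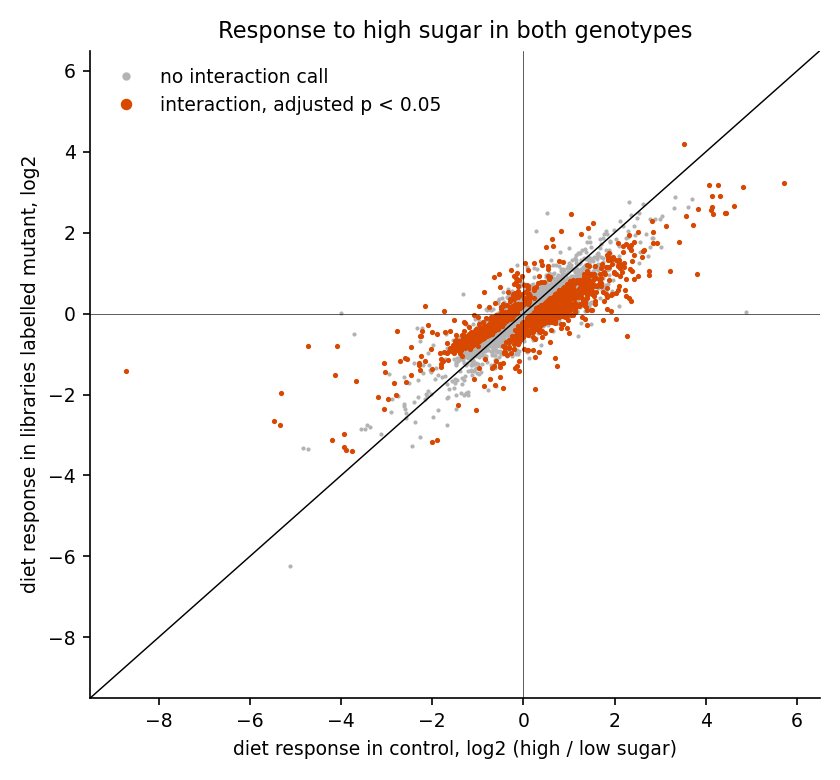
Diet response of each of 9837 genes as the log2 ratio of high to low sugar, in control (horizontal axis) and in libraries labelled mutant (vertical axis), with the 1659 genes that had an interaction in orange and the line of equal response in black. The SD of the responses was 0.668 in control and 0.466 in libraries labelled mutant with the error removed, so the orange points lie mostly between the line and the horizontal axis.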

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

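The tests of the labels, of the release of clock genes, of the low-sugar baseline and of splits without additive effects were chosen only after the result was seen, and the rules behind the tests of depth and of moult stage were tightened after their values were seen, as were those for the release of clock genes and for library scaling. In each group of 4 libraries, a value was picked out where the gap of the highest or lowest library to the nearest other exceeded Dixon's 95% limit as a share of the range, which chance gives in about 1 in 20 groups. Of 380 groups, 28 passed (7.37%), and the number depends on which genes are named. The library and the gap are given. Among control low-sugar libraries, the highest value stood apart for Cyp12a4 (library 4, 0.865), Cyp6w1 (library 1, 0.860), GstD8 (library 4, 0.858), Hsp70Bb (library 1, 0.856), Lcp2 (library 4, 0.888), phu (library 1, 0.886) and Uro (library 3, 0.82926) and the lowest stood apart for Eno (library 2, 0.913) and SdhC (library 4, 0.938). Among control high-sugar libraries, the highest value stood apart for CR45190 (library 4, 0.957), Gad1 (library 3, 0.908), GstD8 (library 2, 0.846) and yip2 (library 3, 0.860) and the lowest stood apart for Cyp6w1 (library 1, 0.919). Among labelled mutant low-sugar libraries, the highest value stood apart for AcCoAS (library 2, 0.975) and ng2 (library 3, 0.854) and the lowest stood apart for cwo (library 1, 0.876), Gad1 (library 1, 0.907) and thetaTry (library 4, 0.875). Among labelled mutant high-sugar libraries, the highest value stood apart for GstD8 (library 2, 0.910) and MtnC (library 2, 0.857) and the lowest stood apart for Amy-p (library 3, 0.858), CG14424 (library 1, 0.841), Mf (library 4, 0.886), Mondo (library 2, 0.834) and Zw (library 3, 0.889). The Tweedle score stood apart in control low-sugar library 1 (0.916), and the recovered depth in labelled mutant high-sugar library 1, at 48.5 M reads against 50.7 to 50.9 in the others (0.880). Control low-sugar libraries 1 and 4 each held 4 of these values, and no other library more than 3.

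The diet response differed between the genotypes, by the test of the interaction, in 1659 genes, of which 54 are among those named for the other comparisons, and in 14 lists by camera at the preset correlation, none of which was called with an estimated correlation (6 had an unadjusted p under 0.05). Genes of fat synthesis and fatty acid oxidation had interactions of -0.96 (AcCoAS), -0.68 (FASN1), -0.68 (FASN2), -0.65 (ACC) and -0.55 (yip2). Sugar and carbohydrate genes had interactions of -2.83 (CG10924), -1.94 (Mal-A7), -1.57 (Mal-A1), -0.44 (fbp), -0.34 (PCB), -0.97 (Gpo-1), -0.47 (Gpdh), -0.39 (Zw), 0.41 (UGP), 0.37 (Amy-p) and 0.65 (Amy-d). Amino acid genes had interactions of -1.64 (aay), -1.15 (hgo), -0.83 (CG11796), -0.78 (Gs1) and -0.29 (Gdh). Detoxification genes had interactions of -1.92 (GstD8), -1.06 (GstE7), -0.42 (GstE5), -0.66 (Cyp6a17) and 0.86 (Cyp28d2). Digestive proteases and lysozymes had interactions of -1.0007 (thetaTry), -0.94 (alphaTry), -0.60 (Jon44E), 0.72 (Jon65Ai), 0.62 (LysD) and 0.95 (LysE). Ribosome biogenesis genes had interactions of 0.39 (nclb), 0.50 (ppan), 0.59 (Fib) and 0.77 (Nop56). Cuticle, salivary, nervous system, muscle and clock genes had interactions of -0.78 (Cpr67Fa1), -0.46 (Cpr60D), -1.02 (ng1), -1.09 (ng2), -0.35 (Gad1), -0.34 (Eaat1), -0.20 (up) and -0.24 (Pdp1). Other genes were CR45190 (-2.48), CG1774 (-1.67), CG4269 (0.68), CG11892 (1.03), Hsp70Bb (1.21), Alp2 (1.28), CG10474 (1.83), CG10514 (2.35), CG32793 (3.35) and CG14422 (7.32). The copies and neighbours among them (Amy-p and Amy-d, the lysozymes, ng1 and ng2, Hsp70Bb, and CG14422 with CG32793) are uncertain, since reads can be shared. Low levels in libraries labelled mutant also limit the reading of ng2, CG14422 and CG10514. The call of Amy-p held in the fits without control low-sugar library 1 or 4, control high-sugar library 3, labelled mutant low-sugar library 1 or 4 or labelled mutant high-sugar library 3. It ended in the other 10 fits that left out 1 library (0.32 to 0.37) and with a pseudocount of 2 CPM (0.31, adjusted p = 0.0583), and that of ng1 ended with a pseudocount of 0.1 CPM (-0.97, adjusted p = 0.0582). The median interaction of a list, all called only at the preset correlation, was -0.30 for fatty acid synthesis, -0.18 for fatty acid oxidation, -0.44 for gluconeogenesis, -0.31 for digestive serine proteases, -0.25 for cytochrome P450 and -0.38 for glutathione S-transferases. It was -0.44 for cuticle proteins, -0.29 for chitin metabolism, 0.46 for ribosome biogenesis and 0.0771 for the proteasome. Among marker lists it was -0.23 for neuron, -0.32 for midgut enterocyte, -0.85 for salivary gland, and -1.02 for epidermis and cuticle.

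The level of cwo RNA was higher in all 8 libraries labelled mutant. Single libraries with exchanged labels are argued against by the gene w, for which 0 of the 16 libraries lay on the side of the other genotype. An exchange of the labels as a whole cannot be told apart from correct labels, because no mark of the allele itself is in values per gene, and w, with at least 316 CPM in libraries labelled mutant, marks only the strain. A release of clock genes that Clockwork orange represses, its own gene included, cannot be told apart from other sources of the direction: of tim, vri and Pdp1, 2 were higher on both diets, and of 11 clock genes on low sugar 7 did not pass and 1 was lower. The strain background, which differs at least in w, stays open as well.

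The diet response was smaller in libraries labelled mutant, with a ratio of the SDs of 0.698 (0.672 to 0.735 when 1 library was left out). Library scaling, moult-gene differences and the male share of the larvae are argued against as its whole cause, since the ratio was 0.697 with quantile normalization, 0.705 with the Tweedle score as a covariate and 0.705 with roX1 as a covariate. A candidate explanation is a low-sugar baseline that already lies towards the high-sugar state, since the genotype effect on low sugar had a slope of 0.317 (jackknife SD 0.0674) on the average diet effect and that on high sugar -0.041 (0.0356), although these slopes and the ratio are linked by construction. It is argued against in ribosome biogenesis, where the median genotype effect on low sugar was 0.0778 (0.0062 to 0.145 when 1 library was left out, SD over 19 genes 0.207) while such a baseline needs -0.464. Of the 10 lists called in control with an interaction against that change, 4 (ribosome biogenesis, cytochrome P450, glutathione S-transferases and fatty acid synthesis) were called between genotypes on high sugar alone, 5 on low sugar alone and 1 on both, so the slope over all genes does not hold for each list, and whether cwo, the strain background or a difference in stage lies behind it stays open.

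Cuticle genes differed between libraries of the same group, with Tweedle scores in control low sugar of 5.26 in library 1 and 3.27 to 3.43 in the others. The male share of the larvae is argued against, since the score had r = -0.027 with roX1 within groups (16 libraries, exact permutation test, two-sided p = 0.930, adjusted over 2 relations 0.985; rho = 0.05, p = 0.932; r = 0.00615 without the 2 farthest libraries). Library depth cannot be told apart from other sources of the spread: r was 0.00632 (exact permutation p = 0.985), but rho was -0.45 (exact permutation p = 0.145) and r was -0.418 without the 2 farthest libraries, so the bound set on r alone was too weak. Moult stage cannot be told apart either: 2 of 16 genes of the ecdysone list moved with the score and 1 against it, Eip74EF among the former (slope 0.79, adjusted p = 5.69e-04). The ecdysone list passed in camera (adjusted p = 0.0368) and not with an estimated correlation (adjusted p = 0.895), as did chitin metabolism, with the score, and ribosome biogenesis (adjusted p = 4.76e-05), proteasome, oxidative phosphorylation and pentose phosphate pathway, against it (0.0368 for each other list, 0.895 for all with an estimated correlation), so the ecdysone list does not stand out.

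Other divisions of the libraries were refitted. Each diet response and each genotype effect had 35 splits of the 8 libraries compared. No other split called as many genes as the real one, and the highest called 1, 53, 4 and 0, in the order of the report. With 35 splits, of which the others mix groups that differ and so can call fewer genes, chance is unlikely but not excluded. For the interaction, with additive effects of genotype and diet removed, the real one of 100 drawn splits within each diet gave 1659 genes. The others gave at most 1 but hold any interaction as spread, leaving chance open. With these effects kept, the 5 highest others called 498 to 1345, all with 2 pairs exchanged in 1 diet, which carried along the genotype difference on the other.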

How the results depend on the processing

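The fits without the 4 libraries of high Tweedle score or 4 others, with the Tweedle score or roX1 as a covariate and with array weights were chosen after the data were seen, as were the relations, odds ratios and genes followed here. Across 399 pairs of gene and comparison and 29 alternatives, 8709 values kept their direction and side of the threshold, 126 lost the call, 40 gained one and 25 turned sign, of which only ATPsynbeta and SdhA were called as reported. The cause was not tested. The planned tests for counts on recovered reads were not run.

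Without the 4 libraries of high Tweedle score limma called 6248, 4749, 3692 and 3492 genes in the 4 comparisons of groups and 790 with an interaction, against 1659. Without 4 other libraries, 1 per group, the medians over 81 choices were 6045, 4265, 3240, 3099 and 690 (interactions 529 to 1963), so fewer libraries alone can give such counts. With an estimated correlation camera called 0 lists in each of the 5 comparisons, against 19, 18, 14, 10 and 14, and at an unadjusted p under 0.05 it called 2, 6, 3, 3 and 6. fry called 35, 28, 27, 24 and 15 lists by direction and 38, 36, 39, 36 and 28 without regard to it. The odds ratio within 1 Mb of cwo on low sugar was 1.42 with quantile normalization (adjusted p = 0.0770) and 1.28 without the libraries of high Tweedle score (adjusted p = 0.230). It passed on high sugar with median-ratio scaling (1.37) and for the interaction with that scaling (1.5033), roX1 (1.53) and array weights (1.55). Within 5 Mb it was 0.997 on low sugar with only the 8 libraries compared and 0.934 without the libraries of high Tweedle score, 0.989 on high sugar without these and 0.998 with roX1, and 1.24 for the interaction with array weights.

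The other values that turned sign lay close to 0 as reported. The genotype effect of vri on low sugar was -0.00462 with a pseudocount of 2 CPM, -0.0228 with the Tweedle score and -0.00589 with roX1. That of cbt was 0.00368 without the libraries of high Tweedle score, 7.48e-04 with roX1 and 0.0271 with array weights. That of fkh on high sugar was -0.0344 with quantile normalization, -0.00554 with the Tweedle score and -0.105 with roX1. The interaction of tim was 0.383 with a pseudocount of 2 CPM and 0.0472 with quantile normalization. With quantile normalization the diet response in libraries labelled mutant was -0.0241 for ATPsynbeta and -0.00882 for SdhA.

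Leaving out each library in turn gave 6302 to 6496, 4608 to 5233, 3807 to 4850 and 3450 to 3633 genes in the 4 comparisons and 1196 (without control high-sugar library 4) to 2451 (without labelled mutant low-sugar library 1) interactions. The correlation of the diet responses was 0.831 to 0.858, lowest without labelled mutant low-sugar library 1, the SD ratio 0.672 to 0.735, and the share of all interactions that went against the diet effect, with or without a called diet effect, 84.003 to 88.8% (86.9% with all libraries). The odds ratios were 1.35 to 1.71, 1.24 to 1.39 and 1.28 to 1.58 within 1 Mb and 0.981 to 1.07, 0.953 to 1.05 and 1.03 to 1.17 within 5 Mb, on low sugar, on high sugar and for the interaction. The values that turned sign ranged over -0.061 to 0.0376 (cbt, low sugar), -0.208 to 0.314 (vri, low sugar), -0.0142 to 0.0248 (fkh, high sugar) and -0.147 to 0.0109 (interaction of tim).

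The groups share replicate numbers, and the labels give them no meaning. The 24 pairs of same-numbered libraries had deviations from the group means with r between -0.340 and 0.437 (mean 0.107), 13 of them over 0.1, against a mean of -0.027 and 26 over 0.1 among 72 other pairs. All 6 pairs of number 2 lay over 0.1 (0.141 to 0.437), against 2, 3 and 2 of 6 for numbers 1, 3 and 4, and 5 of 16 libraries matched their own number best. Pairing by all numbers is not shown, and a link among libraries of number 2 stays open. With the replicate block limma called 6830, 5400, 4629, 4229 and 1949 genes, and camera 20, 18, 13, 11 and 14 lists, and the interaction of cwo passed (0.37, adjusted p = 0.0478).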

Other observations

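The tests of neighbouring genes and the genes tobi, Amyrel, Drsl2 and the members of the runs were chosen only after their values were seen. The glucosidase gene tobi, known to respond to diet, stood at 14.6 ± 1.97 and 7.79 ± 1.05 CPM in control on low and high sugar and at 0.221 ± 0.0911 and 0.548 ± 0.137 in libraries labelled mutant, so that it was lower by 4.39 ± 0.13 and 2.99 ± 0.13 on the log2 scale. The amylase-related gene Amyrel fell with sugar by 3.18 ± 0.14 in control and 2.06 ± 0.14 in libraries labelled mutant. Of 14 amylases and maltases, 7 rose, 6 fell and 1 did not pass (7 and 6 over the list alone) with sugar in control, and 6 fell, 5 rose and 3 did not pass (6 and 5 over the list alone) in libraries labelled mutant (adjusted p = 0.936, adjusted p = 0.963 with an estimated correlation in control, adjusted p = 0.760, adjusted p = 0.947 with an estimated correlation in libraries labelled mutant). The Drosomycin-like gene Drsl2 was lower in libraries labelled mutant, by 4.31 ± 0.18 on low and 4.31 ± 0.18 on high sugar.

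Among digestive serine proteases on high sugar the median difference between genotypes was -0.10 while the mean was 0.23 and camera gave the direction up, so the list has no common direction there (adjusted p = 0.474). Cuticle genes that moved most with the Tweedle score within groups, apart from the Tweedle genes themselves, included Ccp84Ae (slope 1.93 ± 0.19 per log2 unit of the score, SE, 16 libraries), Ccp84Ac (1.504 ± 0.12) and Ccp84Af (1.49 ± 0.10). limma called 219 genes on the score, 205 with it and 14 against it.

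Genes changed at least 2-fold were often direct neighbours with the same direction. On the X chromosome from 2925884 to 2946589 (BDGP6), the 6 adjacent genes CG14424, CG32793, CG3598, CG14420, CG14422 and CG14423 fell with sugar in control (median -5.33) and were lower in libraries labelled mutant on low sugar (median -4.15), and 5 of them had a positive interaction (median 3.35). The call of CG14420 (2.59 ± 0.83, adjusted p = 0.0443) held in the fits without control high-sugar library 1 or 2 or labelled mutant low-sugar library 1 and ended in the other 13 that left out 1 library (2.18 to 2.74). That of CG3598 (2.82 ± 0.84, adjusted p = 0.0322) ended without library 1 or 3 of control low sugar, 3 or 4 of control high sugar, 2 or 4 of labelled mutant low sugar or 2 or 3 of labelled mutant high sugar (2.31 to 2.79). Both ended with a pseudocount of 0.1 CPM (1.81 and 2.24), with roX1 as a covariate (2.50 and 2.55) and without the 4 libraries of high Tweedle score (1.59 and 1.69, against 1.97 to 3.74 and 2.16 to 3.94 without 4 others), and that of CG14420 in the robust fit (adjusted p = 0.0661). On 3R from 25275790 to 25288930, CG10513, CG10514, CG11892, CG31104 and CG13658 were lower in libraries labelled mutant on low sugar (median -3.48). On 2L from 3039976 to 3068177, CG17221, CG17261, FASN2 and FASN1 rose with sugar in both genotypes (medians 2.07 and 1.58), and the mannosidase genes LManIII, LManIV, LManV and LManVI fell (medians -1.75 and -1.84). Neighbours can be copies that share reads.

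The number of such neighbouring pairs was 142, 53, 102, 61 and 17 in the 5 comparisons, in the order of the report, against means of 44.7, 8.81, 18.1, 9.64 and 1.45 and highest values of 69, 21, 37, 23 and 8 over 10000 permutations of gene order. Each permutation p was 1e-04, the smallest these can give. Changes called in both the authors' deposited table and the refit numbered 6638, 5080, 4282 and 3875, all with the same direction.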
